A study of Mus musculus with 6 samples.

How the data were processed

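RNA from the branching and the non-branching region of the E11.5 mouse lung was measured on 6 arrays, 3 per region, with 1 sample per array. The values are the deposited intensity of each probe set on a linear scale, 1 column per array. What the authors did to compute them is not given in the sources used here. In the deposited intensity values, the mean of each array without the lowest and highest 2% of its values was 500.3, so the arrays had already been scaled to a common level, as read from the values alone. The array medians ran from 212 to 229, a ratio of 1.08, and the deposited scaling was kept. The values ran from 0.4 to 132374, and no detection calls were used here. Probe sets are groups of short oligonucleotides designed against 1 transcript, and the names of some mark designs that are less specific for that transcript. Among the genes named below, Sox2, Bmp4, Col2a1, Mfap4, Cnn1, Actc1, Tnnt1 and Mpo were represented by such a less specific probe set.

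Of 12488 probe sets, 66 controls were left out. In the platform's annotation table, 10833 of the remaining 12422 had 1 gene symbol, 396 had several and 1193 had none, and 10817 had a gene identifier that matched a table of mouse RefSeq genes, which changed no symbol. A probe set with several symbols was tested but not named. A gene with several probe sets was represented by the one with the highest mean log2 signal over the 6 arrays, and other probe sets that were tested were reported where their difference had the other sign or was below 0.1 in size. No genome build is given in the sources used here, so no coordinates are printed.

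Values below 16 were set to 16 and log2 was taken. On each array 5.01% to 8.26% of the values lay at this floor. The 25% of probe sets with the lowest mean log2 signal were left out, and the other 9316 were tested with limma 3.58.1 in R 4.3.3 (lmFit on the 2 groups, eBayes with a trend of the variance on mean signal, two-sided). P-values were adjusted by the Benjamini-Hochberg method, and a probe set was called at an adjusted p under 0.05. Differences are branching minus non-branching on the log2 scale with the standard error of the moderated fit, and they understate the change of dim genes because of the floor. Mean signals are on the linear scale with the SD of the 3 arrays. The background level of 147 is the 95th percentile of 114 values from 19 control probe sets for bacterial and yeast transcripts. Where a group was at or below this level on all 3 arrays or in its mean, the change of a called gene is given as at least the fold between the mean log2 signals with each array of that group raised to the background level. The adjusted p is that of the fit. For such a gene that was not called, no fold or difference is given.

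The sets of genes described were 28 lists, of which 26 had at least 5 tested members and were tested with limma's camera with a preset correlation of 0.01 between genes, adjusted over the 26 lists. With this setting 3 lists were higher and 8 lower in branching, and with a correlation estimated for each list 2 passed, those of the interstitial matrix and the cell cycle. By limma's fry, which asks whether the genes of a list move on balance in 1 direction without comparing them with other genes, 12 lists passed. The lists covered regions and tissues of the lung, signalling pathways, growth, and the cell types that a dissected sample may hold besides the lung (neuronal, cardiac, skeletal muscle, endothelial, red blood cell, leukocyte, hepatic and gut, thyroid and thymus). Some genes are in more than 1 list. The groups, the test, the lists, the rule for naming genes and the alternatives were fixed before the data were examined. Named genes were the 12 largest rises and 12 largest falls among genes with 1 symbol that were called and whose groups did not overlap, 13 landmark genes of the early lung, and in each list up to 4 called members with the largest change, or the 2 with the smallest p where none was called. For a named gene that lost its call when an array was left out, the omission with the highest adjusted p was reported. Other omissions could also end the call of such a gene.

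The tests were tested on simulated data for this comparison, with 200 changed probe sets among 9316 tested. Of probe sets changed 2-fold 23.7% were recovered, and of those changed 4-fold 73.8%. No recovered probe set had the wrong sign, 5.62% of the calls were unchanged probe sets, and 0 probe sets and 0 lists were called in data without change. The noise was drawn independently for each probe set, so these data cannot show how the list tests behave when genes vary together. The alternatives were the replicate number as a block, quantile normalization, centring each array on its median, no filter on dim probe sets, leaving out the dimmer 50%, a floor of 64, adding 16 in place of the floor, no variance trend, array weights, a test of each probe set on its own, an adjusted p under 0.10, a minimum of 2-fold, other list tests, the mean of a gene's probe sets, and leaving out each array in turn. No array batches or dates are given in the sources used here. Figures were drawn with matplotlib 3.10.9.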

Results

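Gene expression was measured in the lungs of mouse embryos at embryonic day E11.5, a stage at which side branches are forming on the left and the right lung. RNA was taken from 2 dissected regions. The branching region came from the lungs of both sides. The non-branching region held the main bronchi together with a piece of the trachea. Each region was measured on 3 arrays, 1 sample per array, named here by region and replicate (1 to 3). The labels do not say whether the replicates came from separate embryos or litters. The p-values of single genes therefore measure only the spread between these samples, which may be technical. Camera p-values with the preset correlation set the genes of a list against the other genes and do not measure the spread between samples. Each array gave a signal for 12488 probe sets, and the number of arrays limits the precision of each value.

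No test of array level or RNA quality found a difference between the regions, but with 3 against 3 arrays none could reach a p under 0.05. The median signal was 215 ± 4.71 (SD, n = 3) on the branching arrays and 221 ± 7.2 on the non-branching arrays (two-sided exact permutation test, p = 0.4, where 0.1 is the smallest p that 3 against 3 arrays allow). The log2 difference between the 3' and 5' control probe sets, a measure of RNA integrity, was -0.06 ± 0.10 in branching and -0.12 ± 0.07 in non-branching for Gapdh (exact permutation p = 0.5), and 0.32 ± 0.13 and 0.51 ± 0.23 for actin (exact permutation p = 0.4). Single arrays stood apart. The actin difference was 0.75 on non-branching replicate 3 and 0.20 to 0.49 on the other arrays. The median of the bacterial and yeast control probe sets was 78.8 on non-branching replicate 2 and 19.8 to 40.7 on the other arrays. Across genes, the log2 signals of arrays of the same region correlated at 0.899 to 0.918 and those of different regions at 0.880 to 0.907. The first principal component held 27.4% of the variance and separated the regions, with branching arrays at 16.9 to 34.0 and non-branching arrays at -33.5 to -11.7.

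The comparison asked which genes differ in expression between the branching and the non-branching region. The branching region had more signal from the transcription factor genes Hoxb5, Gata5, Cebpb and Mybl2 and from the DNA replication gene Rrm2. The non-branching region had more signal from the elastin gene Eln, the type I collagen gene Col1a2, the smooth muscle genes Acta2 and Myh11 and the mesenchymal transcription factor genes Tcf21 and Six2. Of 9316 probe sets tested with limma, 84 were higher and 105 lower in branching at an adjusted p under 0.05. With 1 probe set per gene, 68 genes were higher and 90 lower among 6798 tested, and 15 called probe sets had no single gene symbol. The median absolute change of the called probe sets was 0.87 on the log2 scale, and 24 of the higher and 51 of the lower ones differed at least 2-fold. No gene had probe sets called in opposite directions, and the median log2 difference of all probe sets tested was -0.0046. Of the 158 genes called, 42 (14 higher and 28 lower) passed whichever array was left out, and 19 passed without a trend of the variance on signal. Of the genes named above, Hoxb5, Rrm2, Col1a2 and Acta2 did not pass without that trend. Without that trend limma called 5 probe sets higher and 17 lower, and without the filter on dim probe sets 38 and 62. The counts of higher and lower probe sets were 52 and 98 without branching replicate 1, 40 and 77 without branching replicate 2, 16 and 56 without branching replicate 3, 69 and 60 without non-branching replicate 1, 35 and 50 without non-branching replicate 2, and 23 and 38 without non-branching replicate 3.

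**Figure D1:**
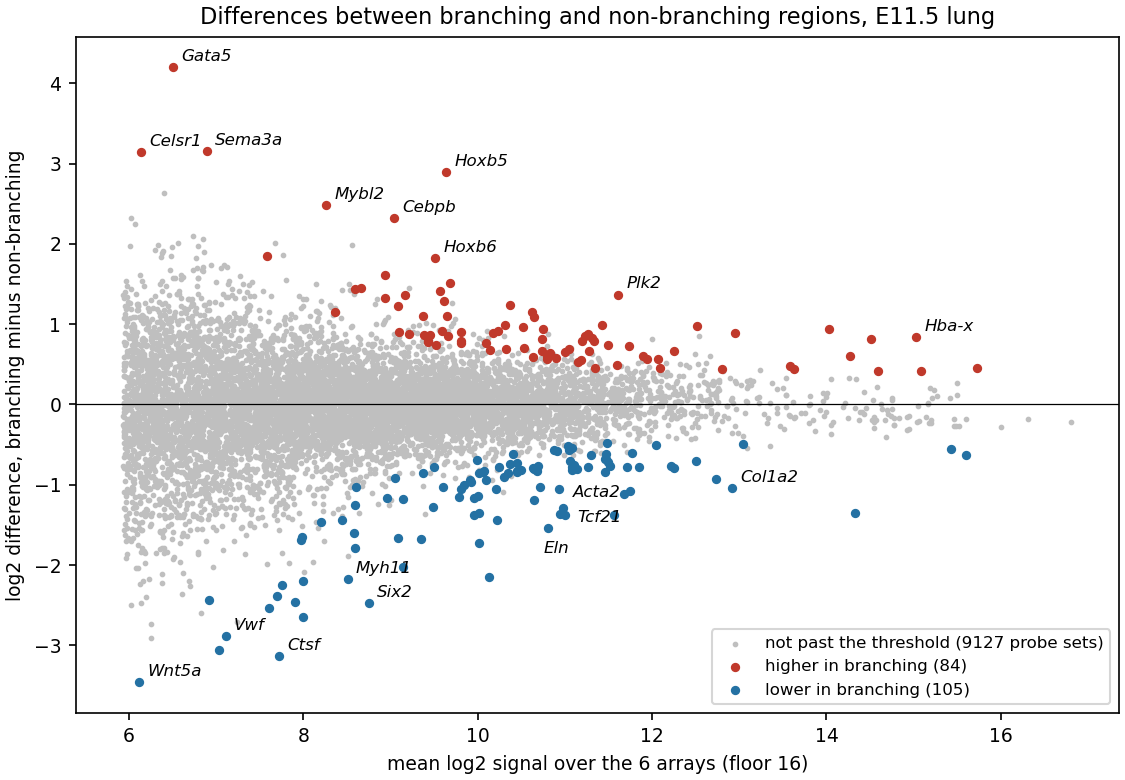
Each point is 1 of the 9316 probe sets tested, with the mean log2 signal over the 6 arrays on the x axis and the log2 difference (branching minus non-branching) on the y axis. Red points are the 84 probe sets higher and blue points the 105 lower in branching at an adjusted p under 0.05 (limma, 3 arrays per region), with selected genes named.

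Among the 12 genes with the largest rise in branching, Hoxb5 (Entrez gene 15413) rose by 2.90 ± 0.41 on the log2 scale (SE, n = 3 per region, limma adjusted p = 0.00851), from a mean signal of 334 ± 176 (SD) in non-branching to 2175 ± 237 in branching. Its neighbour in the same cluster, Hoxb6 (Entrez gene 15414), rose by 1.82 ± 0.26 (adjusted p = 0.00923). Cebpb (Entrez gene 12608), a leucine zipper transcription factor gene, rose by 2.32 ± 0.21 (adjusted p = 0.00104), from 239.6 ± 51.3 to 1181 ± 105. Mybl2 (Entrez gene 17865), a transcription factor gene of dividing cells, rose at least 4.73-fold (adjusted p = 0.00271), a lower bound because its mean in non-branching was below background, while its other probe set, of a less specific design, differed by 0.09 (adjusted p = 0.931). Plk2, which encodes a polo-like kinase, rose by 1.37 ± 0.12 (adjusted p = 0.00112), from 1949 ± 87.0 to 5076 ± 831. Car2, a carbonic anhydrase gene, rose by 1.51 ± 0.14 (adjusted p = 0.00122), Phlda1 by 1.61 ± 0.22 (adjusted p = 0.00799) and Dusp9, a MAP kinase phosphatase gene, by 1.44 ± 0.23 (adjusted p = 0.0144).

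A further 4 of these 12 genes were at background in non-branching on all 3 arrays, so their change is a lower bound. Gata5 (Entrez gene 14464), which encodes a zinc finger transcription factor, was at least 2.64-fold higher in branching (limma adjusted p = 0.00366), with mean signals of 393 ± 67.3 in branching and 22 ± 7.78 in non-branching (SD, n = 3). Sema3a, a secreted guidance ligand gene, was at least 2.41-fold higher (adjusted p = 0.0246), Ror1, a receptor tyrosine kinase gene, at least 2.48-fold (adjusted p = 0.0277), and Celsr1, a planar cell polarity cadherin gene, at least 1.43-fold (adjusted p = 0.0239). By the rule that chose the 12 genes, the 3 branching values of each lay above its 3 non-branching values. Gata5, Hoxb5, Mybl2, Cebpb, Car2 and Plk2 stayed past the threshold whichever array was left out. Without the variance trend Hoxb5 (adjusted p = 0.115) and Plk2 (adjusted p = 0.0665) did not pass, nor did Hoxb5 with no filter on dim probe sets (adjusted p = 0.0739), and with each probe set tested on its own Car2 was the 1 of these 6 that passed. Without branching replicate 3 the adjusted p was 0.120 for Sema3a, 0.144 for Ror1, 0.0810 for Dusp9, 0.0512 for Hoxb6 and 0.0512 for Phlda1. Without non-branching replicate 2 it was 0.0567 for Celsr1. Sema3a and Ror1 passed in 1 of the 6 omissions, Dusp9 in 2, and Hoxb6 and Phlda1 in 5. Celsr1 passed in 0 of the 3 omissions that tested it.

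Among the 12 genes with the largest fall in branching, Six2 (Entrez gene 20472), a homeobox gene of mesenchymal progenitors, fell by 2.47 ± 0.25 on the log2 scale (SE, n = 3 per region, limma adjusted p = 0.00142), from a mean signal of 1038 ± 285 (SD) in non-branching to 183 ± 16.8 in branching. Myh11 (Entrez gene 17880), the smooth muscle myosin heavy chain gene, fell by 2.18 ± 0.23 (adjusted p = 0.00175), from 776 ± 73.6 to 172 ± 26.3. In branching, the mean and 2 of 3 arrays were below background for the transcription factor genes Foxc2, at least 3.81-fold lower (adjusted p = 0.0211), and Twist1, at least 3.18-fold lower (adjusted p = 0.0246), and for Cyp1b1, a cytochrome P450 gene, at least 3.11-fold lower (adjusted p = 0.0219). In branching, the other 7 genes were at background on all 3 arrays. Ctsf (Entrez gene 56464), which encodes a lysosomal protease, was at least 4.25-fold lower in branching (adjusted p = 0.00142), with 71.3 ± 4.49 against 638 ± 159. The retinoic acid receptor gene Rarg and the retinoic acid binding protein gene Crabp1 were at least 3.81-fold (adjusted p = 0.00552) and at least 3.72-fold lower (adjusted p = 0.00584). Col8a1, a short-chain collagen gene, was at least 3.23-fold lower (adjusted p = 0.0120), the endothelial gene Vwf at least 2.55-fold (adjusted p = 0.00851), the zinc finger gene Zfp467 at least 1.91-fold (adjusted p = 0.0277) and the ligand gene Wnt5a at least 1.57-fold (adjusted p = 0.0175).

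By the rule that chose these 12 genes, the 3 branching values of each lay below its 3 non-branching values. Ctsf, Six2, Rarg, Crabp1 and Myh11 stayed past the threshold whichever array was left out, but none of these 5 passed with each probe set tested on its own. Without non-branching replicate 2 the limma adjusted p was 0.0604 for Vwf, 0.0996 for Foxc2, 0.106 for Twist1 and 0.0655 for Col8a1. Without non-branching replicate 3 it was 0.164 for Zfp467 and 0.0976 for Cyp1b1, and without branching replicate 3 it was 0.0553 for Wnt5a. Vwf passed in 5 of the 6 omissions, Col8a1 in 3, Twist1 and Cyp1b1 in 2, Foxc2 in 1 and Zfp467 in 0. Wnt5a passed in 2 of the 4 omissions that tested it.

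Of the landmark genes of the early lung, Acta2, the smooth muscle actin gene, fell by 1.29 ± 0.16 on the log2 scale in branching (SE, n = 3 per region, limma adjusted p = 0.00503), from 3194 ± 697 to 1294 ± 141 (SD), and passed with any 1 array left out but not without the variance trend (adjusted p = 0.108). Sftpc, the surfactant protein C gene of the tip epithelium, had a mean signal of 757 ± 93.9 in branching and 227 ± 133 in non-branching, a log2 difference of 1.99 ± 0.49 that did not pass (adjusted p = 0.0807). Without non-branching replicate 2, whose signal was 74.5, the difference was 1.31 and the adjusted p 0.0364. Sox2, a gene of the proximal airway epithelium read by a less specific probe set, did not pass (adjusted p = 0.0995). Its mean signal was 133 in branching, below background, and 327 in non-branching. The endodermal transcription factor gene Foxa2 differed by -0.62 ± 0.15 and did not pass either (adjusted p = 0.0751). The differences of the ligand genes Shh (0.21 ± 0.20, adjusted p = 0.716) and Bmp4 (0.04 ± 0.14, adjusted p = 0.931) and of the cartilage collagen gene Col2a1 (0.25 ± 0.28, adjusted p = 0.758) were within about their standard errors. A dimmer probe set of Bmp4, at background in branching, had a higher mean in non-branching (adjusted p = 0.274). Fgf10 had a mean signal of 38.6 over the 6 arrays, below the background level, and was not tested. Nkx2-1, Sox9, Spry2, Tbx4 and Wnt2 were not analysed here, since the annotation used here pairs no probe set with those symbols alone.

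**Figure D2:**
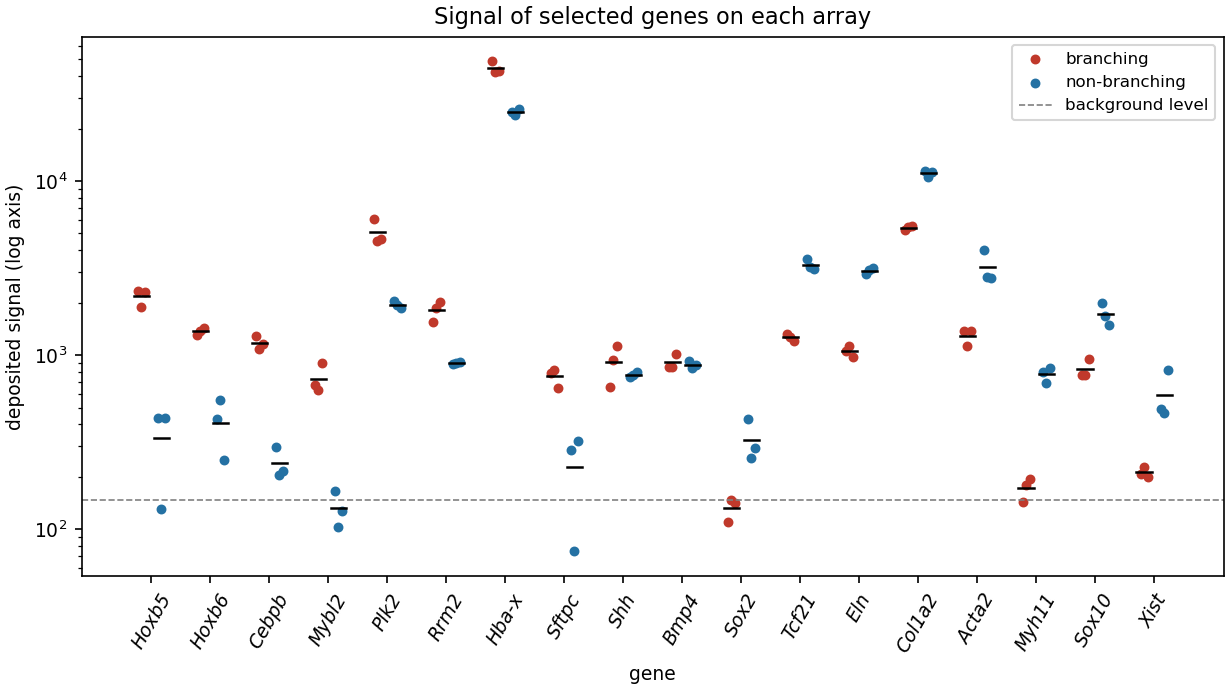
Deposited signal (y axis, log scale) of 18 genes (x axis) on each of the 3 branching arrays (red) and 3 non-branching arrays (blue), with the group mean as a black bar and the background level of 147 as a dashed line. Col1a2 lay near 5394 on the branching and 11085 on the non-branching arrays, while the Bmp4 values of the 2 regions overlapped.

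Genes of the interstitial matrix were lower in branching as a group. Of 31 members tested, 10 fell, none rose and 21 did not pass; adjusted over the list alone, 20 fell and 1 rose. The median log2 difference was -0.74 (limma camera adjusted p = 1.02e-13, and adjusted p = 0.0212 with an estimated correlation). Eln, the elastin gene, fell by 1.54 ± 0.11 (SE, n = 3 per region, limma adjusted p = 4.21e-04), from 3055 ± 116 to 1051 ± 75.6 (SD), and the type I collagen gene Col1a2 by 1.04 ± 0.08 (adjusted p = 5.63e-04), from 11085 ± 432 to 5394 ± 149. The microfibril gene Mfap4 fell by 1.16 ± 0.17 on a less specific probe set (adjusted p = 0.0101). Its other probe set had means below background in both regions (adjusted p = 0.673). The type VI collagen gene Col6a2 fell by 0.97 ± 0.16 (adjusted p = 0.0161). A second probe set of Col1a2, of a less specific design, differed by -0.10 (adjusted p = 0.782). Without non-branching replicate 3 the adjusted p was 0.0534 for Mfap4 and 0.0796 for Col6a2, while Eln and Col1a2 passed with any 1 array left out. Without the variance trend the adjusted p of Col1a2 was 0.0690. Over the same arrays the red blood cell genes were higher in branching, with a median of 0.43.

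Of 18 smooth muscle genes tested, 6 fell, 1 rose and 11 did not pass; adjusted over the list alone, 7 fell and 1 rose. The list was lower in branching (median -0.31, camera adjusted p = 4.32e-05), with an adjusted p = 0.0699 with an estimated correlation. Over the same arrays the median was -0.40 for cardiac muscle genes, -0.42 for neuronal and neural crest genes, -0.26 for endothelial genes and 0.43 for red blood cell genes. Besides Myh11 and Acta2, the calponin gene Cnn1 fell by 2.02 ± 0.36 on a less specific probe set (limma adjusted p = 0.0225). Tagln was 2.01-fold lower (adjusted p = 0.00732). The member that rose was Actn1, which encodes an actin-crosslinking alpha-actinin also found outside muscle (0.49, adjusted p = 0.0422; named after its value was seen). Of 16 cartilage genes, 3 fell and 13 did not pass; adjusted over the list alone, 5 fell and 1 rose. The cartilage list did not pass (median -0.35, camera adjusted p = 0.102). Matn4, a matrilin gene, fell by 1.35 ± 0.13 (adjusted p = 0.00129), Col9a3 by 1.05 ± 0.19 (adjusted p = 0.0225) and Col9a2 by 0.78 ± 0.15 (adjusted p = 0.0322). Of 18 basement membrane genes, 1 rose, 2 fell and 15 did not pass, with the same counts adjusted over the list alone (median -0.19, camera adjusted p = 0.244). The laminin gene Lama5 rose by 0.92 ± 0.15 (adjusted p = 0.0162), although its less specific probe set differed by -0.03 (adjusted p = 0.976). Lama4 fell by 0.86 ± 0.14 (adjusted p = 0.0182), and Agrn, the agrin gene, by 0.54 ± 0.10 (adjusted p = 0.0246). Without non-branching replicate 3 the adjusted p was 0.0995 for Cnn1, 0.0506 for Tagln, 0.0878 for Col9a3, 0.139 for Col9a2, 0.0757 for Lama5 and 0.129 for Agrn. Without branching replicate 3 it was 0.0799 for Lama4. Tagln passed in 5 of the 6 omissions, Cnn1 and Lama5 in 2, and Col9a3, Col9a2, Agrn and Lama4 in 1. The cartilage list passed without branching replicate 1 (adjusted p = 0.0442), with the dimmer 50% of probe sets left out (adjusted p = 0.0245) and by fry (adjusted p = 0.00434).

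Regulators of the lung bud mesenchyme moved both ways. Of 22 tested, 4 rose, 2 fell and 16 did not pass; adjusted over the list alone, 6 rose and 3 fell (median 0.14, camera adjusted p = 0.210, and 0.0268 with the dimmer 50% of probe sets left out). Hoxb5 and Hoxb6 rose, as did Hoxa5 and Lef1, and Twist1 fell (adjusted p = 0.0246, and 0.106 without non-branching replicate 2). Tcf21, a basic helix-loop-helix gene of the lung mesenchyme, fell by 1.38 ± 0.11 on the log2 scale (SE, n = 3 per region, limma adjusted p = 5.63e-04), from 3304 ± 246 to 1267 ± 60.3 (SD), and passed with any 1 array left out. Of 19 genes of the Hox clusters, which include those 3 Hox genes, 3 rose and 16 did not pass; adjusted over the list alone, 5 rose. Hoxa5 rose by 0.76 ± 0.13 (adjusted p = 0.0225, and 0.106 without branching replicate 3). The Hox list was higher in branching (median 0.10, or -0.02 with the mean of each gene's probe sets, mean 0.37, camera adjusted p = 0.0383), with an adjusted p = 0.176 with an estimated correlation and 0.196 by camera on ranks. Its adjusted p was 0.0607 without branching replicate 1, 0.0598 without branching replicate 3 and 0.0936 without non-branching replicate 1, and its median was 0.04 under each of the last 2 omissions.

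Markers of the epithelium showed few changes that passed. Of 18 tip epithelium genes tested, 1 rose and 17 did not pass; adjusted over the list alone, 4 rose and 5 fell, and the list did not pass (median 0.12, camera adjusted p = 0.461). The member that rose was the proto-oncogene Mycn, by 0.85 ± 0.15 on the log2 scale (SE, n = 3 per region, limma adjusted p = 0.0210, and 0.0885 without non-branching replicate 3). None of 12 proximal airway genes passed; adjusted over the list alone, 1 fell (median 0.29, camera adjusted p = 0.357). Sox2 had the smallest p of these, followed by Klf5, a Krüppel-like factor gene that was at background on all 3 arrays in non-branching and on 1 array in branching (adjusted p = 0.157). None of 20 genes shared by epithelia passed; adjusted over the list alone, 1 rose (median 0.08, camera adjusted p = 0.210). The smallest p-values were those of Ezr, the ezrin gene, with a difference of 1.03 ± 0.23 (adjusted p = 0.0640), and Elf3, with 0.70 ± 0.37 (adjusted p = 0.426). None of 5 mesothelial genes passed, also adjusted over the list alone (median 0.25, camera adjusted p = 0.244), with 0.27 ± 0.16 for Upk3b (adjusted p = 0.478) and 0.51 ± 0.34 for Wt1 (adjusted p = 0.557).

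**Figure D3:**
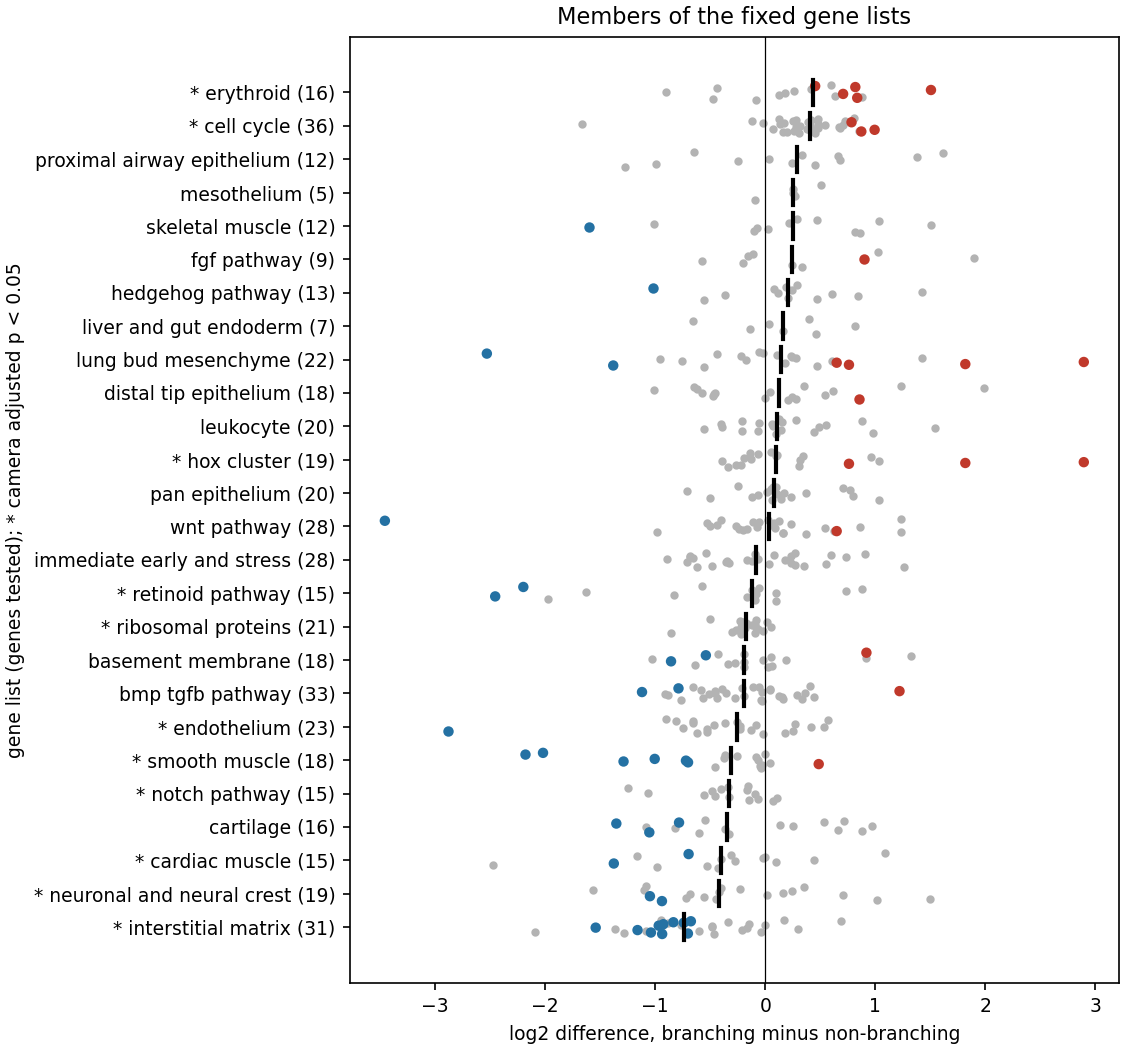
Log2 difference (x axis, branching minus non-branching, 3 arrays per region) of the tested members of the 26 gene lists of at least 5 members (y axis, number of members in brackets), with the median of each list as a black bar. Members higher in branching at an adjusted p under 0.05 are red and those lower are blue, and a star marks the 11 lists past the threshold by camera with the preset correlation, of which the interstitial matrix and cell cycle lists also passed with an estimated correlation.

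In the fibroblast growth factor (FGF) pathway, 1 of 9 genes rose and 8 did not pass; adjusted over the list alone, 2 rose and 1 fell (median 0.25, camera adjusted p = 0.240). The gene that rose was Dusp6, a feedback phosphatase gene of FGF signalling, by 0.90 ± 0.19 on the log2 scale (SE, n = 3 per region, limma adjusted p = 0.0461, and 0.185 without branching replicate 3). Of 13 hedgehog pathway genes, 1 fell and 12 did not pass; adjusted over the list alone, 2 rose and 1 fell (median 0.21, camera adjusted p = 0.240). The gene that fell was Gas1, which encodes a hedgehog co-receptor, by 1.02 ± 0.15 (adjusted p = 0.0106, and 0.0623 without non-branching replicate 3). Ptch1, the hedgehog receptor gene, differed by 0.61 on its brighter probe set (adjusted p = 0.110) and by 1.33 on its other probe set (adjusted p = 0.0138), a pair of values chosen after they were seen. Of 33 genes of the bone morphogenetic protein (BMP) and transforming growth factor beta (TGF-beta) pathways, 1 rose, 2 fell and 30 did not pass; adjusted over the list alone, 1 rose and 5 fell (median -0.20, camera adjusted p = 0.0658). The list passed by fry (adjusted p = 0.0116) and with the mean of each gene's probe sets (adjusted p = 0.0178). Id3, a BMP target gene, fell by 1.12 ± 0.12 (adjusted p = 0.00217), from 4841 ± 479.9 to 2232 ± 289 (SD), and passed with any 1 array left out but not without the variance trend (adjusted p = 0.0928). Bmp1, a procollagen protease gene, fell by 0.79 ± 0.15 (adjusted p = 0.0265), and Tgfbi, a TGF-beta-induced matrix gene, rose by 1.22 ± 0.19 (adjusted p = 0.0138). Without branching replicate 3 the adjusted p of Bmp1 was 0.107 and that of Tgfbi 0.0783.

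Of 28 Wnt pathway genes, 1 rose, 1 fell and 26 did not pass; adjusted over the list alone, 1 rose and 3 fell. The median of the list was 0.04 while its mean was -0.04 and camera pointed down (adjusted p = 0.708), so these differ in sign. Wnt5a was the member that fell (adjusted p = 0.0175, and 0.0553 without branching replicate 3), and the transcription factor gene Lef1 rose by 0.65 ± 0.11 on the log2 scale (SE, n = 3 per region, limma adjusted p = 0.0175, and 0.0757 without non-branching replicate 3). None of 15 Notch pathway genes passed; adjusted over the list alone, 1 fell. The Notch list was lower in branching (median -0.33, camera adjusted p = 0.0448), with an adjusted p = 0.176 with an estimated correlation. Its adjusted p was 0.0607 without branching replicate 1, 0.0951 without branching replicate 2, 0.0778 without non-branching replicate 2 and 0.0708 without non-branching replicate 3. The Notch median was -0.14 without branching replicate 2, and -0.08 with the mean of each gene's probe sets (adjusted p = 0.197). With the dimmer 50% of probe sets left out the adjusted p was 0.0631, and with a floor of 64 it was 0.0503. The smallest p-values in it were those of Hey1, a Notch target gene, with -1.25 ± 0.31 (adjusted p = 0.0844), and Notch3, with -0.40 ± 0.12 (adjusted p = 0.142). Of 15 retinoid pathway genes, 2 fell (Rarg and Crabp1) and 13 did not pass; adjusted over the list alone, 5 fell. The retinoid list was lower in branching (median -0.12, mean -0.56, camera adjusted p = 0.0218), with an adjusted p = 0.176 with an estimated correlation and 0.131 by camera on ranks. Its median was -0.02 without branching replicate 1, -0.26 without branching replicate 3 or non-branching replicate 1, -0.22 without non-branching replicate 2 and -0.30 without non-branching replicate 3.

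Genes of DNA replication and mitosis were higher in branching as a group. Of 36 tested, 3 rose, none fell and 33 did not pass; adjusted over the list alone, 16 rose. The median log2 difference was 0.41 (camera adjusted p = 1.08e-11, and adjusted p = 0.0212 with an estimated correlation). Rrm2, a ribonucleotide reductase subunit gene, rose by 0.99 ± 0.13 (SE, n = 3 per region, limma adjusted p = 0.00661), from 902 ± 8.07 to 1807 ± 234 (SD), and passed with any 1 array left out but not without the variance trend (adjusted p = 0.104). Pcna, the gene of the replication clamp, rose by 0.87 ± 0.16 (adjusted p = 0.0257, and 0.112 without non-branching replicate 3), and the thymidine kinase gene Tk1 by 0.78 ± 0.13 (adjusted p = 0.0160, and 0.0813 without branching replicate 3). The red blood cell genes, higher on the same arrays, had a median of 0.43. None of 21 ribosomal protein genes passed; adjusted over the list alone, 1 fell. As a list they were lower in branching by camera (median -0.18, adjusted p = 6.24e-04), with an adjusted p = 0.249 with an estimated correlation, 0.0696 by fry and 0.0664 with the mean of each gene's probe sets. Random lists matched on mean signal had a median as low in a share of 0.24. These draws could pick the list's own members, so they cannot tell whether the shift is ordinary for genes of that signal. The smallest p-values were those of Rps4x, with -0.30 ± 0.07 (adjusted p = 0.0711), and Rplp0, with -0.27 ± 0.08 (adjusted p = 0.143). A less specific probe set of Rps4x had means below background in both regions, the higher in branching (adjusted p = 0.794).

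Of 16 red blood cell genes tested, 5 rose and 11 did not pass; adjusted over the list alone, 6 rose. The list was higher in branching (median 0.43, camera adjusted p = 4.32e-05), with an adjusted p = 0.0854 with an estimated correlation. Besides Car2, the embryonic globin gene Hba-x rose by 0.84 ± 0.09 on the log2 scale (SE, n = 3 per region, limma adjusted p = 0.00158), from 24980.3 ± 1136 to 44661 ± 3611 (SD). Hba-a1 rose by 0.82 ± 0.08 (adjusted p = 0.00158) and Hbb-b2 by 0.71 ± 0.12 (adjusted p = 0.0219, and 0.103 without branching replicate 3). Without the variance trend the limma adjusted p was 0.115 for Hba-x, 0.115 for Hba-a1 and 0.170 for Hbb-b2. Of 23 endothelial genes, 1 fell (Vwf) and 22 did not pass; adjusted over the list alone, 4 fell. The endothelial list was lower in branching (median -0.26, camera adjusted p = 0.0494), with an adjusted p = 0.226 with an estimated correlation. Its adjusted p was 0.262 without branching replicate 1, 0.120 without non-branching replicate 1 and 0.0799 without non-branching replicate 2, and the call was lost under 12 of the 19 alternatives tried. Its median was -0.05 without branching replicate 1, -0.45 without branching replicate 3, -0.41 without non-branching replicate 2 and -0.16 without non-branching replicate 3. None of 20 leukocyte genes passed, also adjusted over the list alone (median 0.11, camera adjusted p = 0.357), with the smallest p-values for Mrc1 (adjusted p = 0.345), at background in non-branching and with a mean below that level in branching, so that no fold is given, and for Mpo, with a mean below background in non-branching (adjusted p = 0.374). Another probe set of Mpo had means below background in both regions, the higher in non-branching (adjusted p = 0.635).

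Of 19 neuronal and neural crest genes, 2 fell and 17 did not pass; adjusted over the list alone, 2 fell and 1 rose. The list was lower in branching (median -0.42, camera adjusted p = 0.0454), with an adjusted p = 0.176 with an estimated correlation. Its adjusted p was 0.0528 without branching replicate 1, 0.0741 without branching replicate 3, 0.0799 without non-branching replicate 2 and 0.0916 without non-branching replicate 3, and its median was -0.25 without branching replicate 3. The adjusted p was 0.0551 with the replicate number as a block, 0.0539 with quantile normalization, 0.105 by camera on ranks and 0.0984 with the mean of each gene's probe sets. Sox10, a neural crest and glial gene, fell by 1.05 ± 0.15 on the log2 scale (SE, n = 3 per region, limma adjusted p = 0.00974), from 1718 ± 254 to 829 ± 101 (SD), and the neuropeptide gene Gal by 0.94 ± 0.16 (adjusted p = 0.0214, and 0.0920 without non-branching replicate 2). Without the variance trend the limma adjusted p was 0.115 for Sox10 and 0.140 for Gal. A less specific probe set of Gal, at background in non-branching, had a higher mean in branching (adjusted p = 0.671). Of 15 cardiac muscle genes, 2 fell and 13 did not pass; adjusted over the list alone, 3 fell. The cardiac list was lower in branching (median -0.40, camera adjusted p = 0.0111, and 0.0565 without non-branching replicate 2), with an adjusted p = 0.168 with an estimated correlation. Actc1, the cardiac actin gene, fell by 1.38 ± 0.22 on a probe set of a less specific design (adjusted p = 0.0142, and 0.0588 without non-branching replicate 3). Tnni1, a slow troponin gene, fell by 0.70 ± 0.15 (adjusted p = 0.0480, and 0.190 without non-branching replicate 3). Tnni1 passed in 0 of the 6 omissions. Of 12 skeletal muscle genes, 1 fell and 11 did not pass, with the same counts adjusted over the list alone (median 0.25, camera adjusted p = 0.874). This was the slow troponin gene Tnnt1, by 1.60 ± 0.22 on a probe set of a less specific design (adjusted p = 0.00763, and 0.0550 without non-branching replicate 3). Its other probe set, not of that design, differed by 0.56 (adjusted p = 0.555).

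None of 7 hepatic and gut endoderm genes passed, also adjusted over the list alone (median 0.17, camera adjusted p = 0.628). Their smallest p-values were those of Alb, the albumin gene, with a mean below background in non-branching (limma adjusted p = 0.487), and Apoa2, at background in both regions (adjusted p = 0.686). Of the thyroid and thymus genes 3 were tested, too few for a list test, and none passed, the smallest p-values being those of Tshr, at background in both regions (adjusted p = 0.542), and Hhex, with a mean below background in non-branching (adjusted p = 0.652). None of 28 immediate early and stress genes, a sign of tissue handling, passed, also adjusted over the list alone (median -0.08, camera adjusted p = 0.996). Hspa8, a heat shock cognate gene, differed by 0.60 ± 0.15 on the log2 scale (SE, n = 3 per region, adjusted p = 0.0946) and Jund by -0.33 ± 0.09 (adjusted p = 0.128). Of 3 sex-linked genes tested, 1 fell: Xist, the RNA of the inactive X chromosome, fell by 1.44 ± 0.27 (adjusted p = 0.0290, and 0.139 without non-branching replicate 3), from 593 ± 197 to 212 ± 13.7 (SD). In this small list the count adjusted over the list alone was also 1, and Xist lost its call with each of the 6 arrays left out in turn.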

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

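No setting here was added after the results were seen, and no called gene changed direction in any of the settings that tested it, nor did a called list, except that the median of the Hox list was -0.02 with the mean of each gene's probe sets, where its test still pointed up. Medians of lists short of the threshold that changed sign were those of tip epithelium, FGF, Wnt, skeletal muscle, leukocyte, and hepatic and gut genes, and the difference of Bmp4 changed sign too. The main fit called 84 probe sets higher and 105 lower in branching. In their place, the counts were 44 and 70 with the replicate number as a block. With no filter on dim probe sets, where more are tested, they were 38 and 62. They were 5 and 17 by eBayes without trend and 2 and 9 by a plain test of each probe set. At an adjusted p under 0.10 they were 164 and 195, and with a minimum of 2-fold 24 and 51. With 1 array left out, which leaves fewer samples, they ran from 16 to 69 and from 38 to 98. In place of 11 lists past the threshold, 2 passed by camera with an estimated correlation, 7 by camera on ranks, and 7 to 10 with 1 array left out. Among lists that lost their call, the estimated correlation was below the preset 0.01 for smooth muscle (-0.023), Notch (-0.014), Hox (-0.044), neuronal (-0.0044) and cardiac genes (-0.051). For these, that argues against a higher correlation between genes as the cause. It was above 0.01 for retinoid (0.018), endothelial (0.020), red blood cell (0.020) and ribosomal protein genes (0.187). With an estimated correlation, camera also takes its degrees of freedom from the arrays and not from the number of genes, which raises p. The camera p of the interstitial matrix list rose from 3.91e-15 to 8.53e-04 with an estimated correlation of -0.010. So a correlation above 0.01 was not shown to be the cause for the retinoid, endothelial, red blood cell and ribosomal protein lists. For the variance trend and the ranks the cause was not tested. Other counts ran from 79 to 117 higher, from 88 to 138 lower and from 8 to 12 lists. The values gave no sign that the replicate numbers pair the samples, which the labels do not settle. The deviations of same-numbered arrays from their group means correlated at -0.0023, 0.0127 and -0.0150. Of the 6 arrays, 0 deviated most like the other array of its own number.

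Over the named genes, the omissions of 1 array left 341 values on the same side of the threshold, put 136 short of it and 1 past it, and the other settings did so for 655, 137 and 2. Over the lists these were 140, 15 and 1, and 302, 28 and 5. Of the 158 called genes, 15 passed both under every omission and without the variance trend: Gata5, Mybl2, Cebpb and Car2 were higher and Matn4, Tcf21, Eln, Cdo1, Vsnl1, Mgp, Myh11, Crabp1, Rarg, Six2 and Ctsf lower. Why the other genes lost their call was not tested. On each array 38.8% to 42.1% of the values lay at or under the background level.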

Other observations

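The tests in this part, other than the splits of the samples, were chosen only after the results were seen. Genes of ribosome assembly, a list drawn up after called members such as Ncl and Nop56 were seen, were higher in branching. Of 54 tested, 5 rose, among them the nucleolin gene Ncl (0.44 ± 0.08 on the log2 scale, SE, n = 3 per region, limma adjusted p = 0.0229), the polymerase I factor gene Ubtf (0.58 ± 0.11, adjusted p = 0.0290) and Pno1 (0.79 ± 0.15, adjusted p = 0.0312). These calls ended with 1 array left out: the adjusted p of Ncl was 0.107 without non-branching replicate 2, that of Ubtf 0.139 without non-branching replicate 3, and that of Pno1 0.144 without branching replicate 3. Pno1 and Ubtf passed in 0 of the 6 omissions. The hypothesis that the list is higher as a group was tested on the 49 members that were not called. Of these 42 had positive differences, with a median of 0.20 (limma camera adjusted p = 1.95e-05 over the 4 added lists, 4.89e-06 before adjustment, and adjusted p = 0.0369 with an estimated correlation). The red blood cell list rose on the same arrays (median 0.43), and whether red blood cell precursors account for this rise was not tested. Among imprinted genes, Igf2, the growth factor gene, fell by 0.64 ± 0.09 (adjusted p = 0.0101), from 61744 to 39923, and Plagl1, a zinc finger gene, rose by 1.29 ± 0.18 (adjusted p = 0.00851). Without non-branching replicate 3 the adjusted p of Igf2 was 0.0653, and without branching replicate 3 that of Plagl1 was 0.0512. The 15 other members tested had a median of -0.25 (limma camera adjusted p = 0.0348, 0.0174 before adjustment), with an adjusted p = 0.550 with an estimated correlation.

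The guidance ligand gene Sema3a was higher in branching, while its receptor gene Nrp1 fell by 1.15 ± 0.16 (limma adjusted p = 0.00790) and the netrin receptor gene Unc5c by 0.80 ± 0.15 (adjusted p = 0.0315). The highest adjusted p with 1 array left out was 0.120 for Sema3a (branching replicate 3), 0.0506 for Nrp1 (non-branching replicate 3) and 0.1035 for Unc5c (branching replicate 2), each over 0.05. The other 32 axon guidance genes tested had a median of -0.11 (limma camera adjusted p = 0.802, 0.601 before adjustment), so the hypothesis that they are lower as a group stays open. Hk2, the hexokinase gene, rose by 1.10 ± 0.16 (adjusted p = 0.00851, but 0.0508 without branching replicate 3), while the other 13 glycolysis genes had a median of -0.08 and the list test pointed up (limma camera adjusted p = 0.910), which differ in sign, so a rise of the group stays open too.

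Of the 10 splits of the 6 arrays into 3 and 3, 1, the real one, called 189 probe sets, and the highest of the others called 0. The real split put 11 lists past the threshold and the highest of the others 2, so again 1 split reached the real count. With 10 splits the share cannot go below 0.1, which is too few for a share under 0.05.

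The matrix and smooth muscle lists, pooled after their fall was seen (49 genes), had a median of -0.60 (bootstrap interval over genes -0.83 to -0.34). Of 10000 random lists matched on mean signal, the share with a median as low was 1e-04, the smallest these draws can give. Lists pooled for their fall were likely to give a small share. The matched lists themselves had a median of 0.008, so genes of like signal showed no such shift, which argues against a bias that depends on signal level. A dilution of the RNA by red blood cells, whose genes were higher in branching, would lower the markers of all other tissues alike, however the arrays are scaled. The median of the pooled lists lay below that of 192 markers of other tissues by a log2 difference of -0.64 (bootstrap interval over genes -0.87 to -0.35). These intervals resample genes and not arrays, so they leave out the spread between samples. Lists chosen for their fall were likely to show such a gap. Some of the markers, such as Apoa2 and Tshr, lay at background in both regions, where dilution can lower the signal little. The gap therefore cannot decide whether dilution is the whole cause, and dilution stays open. Against the cartilage, neuronal and neural crest, cardiac, endothelial, and thyroid and thymus lists 1 at a time, the interval held 0. The markers of the first of these lists were lower too, with medians of -0.35 (cartilage), -0.42 (neuronal), -0.40 (cardiac) and -0.26 (endothelial). A difference between the regions themselves and a difference in how they were dissected stay open and were not tested.

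The cell cycle list had a median of 0.41 (bootstrap interval over genes 0.28 to 0.48) in branching. The share of matched random lists with a median as high was 1e-04, again the smallest possible, and likely to be small for a list already seen to rise. The matched lists had a median of 0.013, which argues against a bias by signal level. The same draws gave 0.24 for the ribosomal protein list. They could pick that list's own members, so they do not decide whether its shift comes from signal level. No biological explanation of the cell cycle pattern was tested, and a difference between the regions themselves and the share of dividing red blood cell precursors stay open.

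Xist fell in branching, and a different mix of female and male embryos between the regions may account for it. A lower share of female tissue would raise Y-linked genes, and Eif2s3y, read by a less specific probe set and the only one of 3 above background on all arrays, differed by 0.24 (95% interval -0.48 to 0.95), which keeps this open. The Xist signals were 208, 227 and 200.5 in branching and 493, 467 and 821 in non-branching. A regulation of Xist that differs between the regions was not tested.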
